A study of Mus musculus with 47 samples.

How the data were processed

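The series holds 47 samples of mouse E14Tg2A ESCs and EBs, 28 of RNA, 10 of chromatin immunoprecipitation, 8 of immunoprecipitated modified DNA and 1 of ATAC. Groups and replicate numbers came from the sample titles. Per the labels' protocols RNA was depleted of ribosomal RNA and libraries were made with a stranded total RNA kit. Expression of 20 RNA libraries in 10 groups of 2 was analysed, together with 1 list of TDG peaks and 1 of p53 peaks. The 8 RNA samples of day 9 EBs, the modified DNA and ATAC samples and other chromatin samples were not analysed here. A further 4 columns of RPKM at 0 h match no sample and were not used.

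The submitters' processing notes name TopHat, DESeq2, Bowtie, DiffBind and genome builds mm9 and dm3. The gene annotation, the counting tool and the peak caller are not given in the sources used here. Expression was deposited by the authors as RPKM, in one table for each pair of groups, each scaled separately. The authors deposited log2 fold changes with standard errors, and p-values and adjusted p-values, in one table per comparison, with the column names DESeq2 gives per the file headers. Other deposited columns hold the authors' mean normalised counts and, in the peak lists, start and end positions. The authors' signs were siC minus siTdg at 48 h and 96 h and G1 minus SG2M at 0 h, and they are turned here. The authors' median standard errors were 0.141 at 48 h, 0.14 at 96 h and 0.206 in EBs, against 0.186, 0.303 and 0.514 from the spread of each group. In sorted cells they were 0.126 against 0.108 for siC phases and 0.155 against 0.156 for siTdg phases. The names of the authors' tables hold the word paired without saying whether replicates or groups were paired. At 96 h and in EBs the authors' smaller standard errors argue against a model without a term for replicate number. In sorted cells the standard errors do not tell. The authors' calls and those of limma here may therefore come from unlike models. In the authors' table at 96 h 17 gene names had become dates.

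Each RPKM value was turned back into reads with the authors' mean normalised counts and a factor per library read from genes with a single read in a single library. Of the positive values 100.0% came out whole within 0.01 reads, in each of the 5. The 2 tables of sorted cells gave lengths that differed by under 0.1% for 19249 of 19249 genes with reads in both. Each library is therefore whole reads over 1 factor and gene length, which was the condition set for comparing siTdg with siC within a phase. Recovered reads ranged from 20818174 to 41433232 per library. Pairs of libraries were checked for duplicates by a chi-square of reads over genes with at least 10 reads, and no pair was within sampling noise. The lowest value per degree of freedom was 4.63, between replicate 1 of siC and of siTdg at 96 h. Within a group the lowest was 19.4.

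Groups were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), for genes with a mean of at least 0.5 RPKM, with eBayes and a trend. Fold changes are on that scale, which understates changes of low genes. One model held the 8 libraries of 48 h and 96 h, one the 8 sorted libraries and one the 4 EB libraries. Calls are at an adjusted p under 0.05 (Benjamini-Hochberg), two-sided. Replicate number was not a term of the model. In simulated data with the real means and spreads, a 4-fold change was recovered for 59.1% of 66 changed genes in the 48 h comparison (12190 genes) and a 2-fold change for 10.4% of 67. For siC phases (12462 genes) it was 100% and 64.2%, for siTdg within G1 (12462 genes) 92.4% and 61.2%, and for EBs (13300 genes) 0% at both sizes. The simulated noise was independent between libraries, while same-numbered real libraries deviated together. These shares therefore describe the model without a replicate term, not all that these data could show.

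Before the data were examined, 25 gene lists with 799 entries, the tests, the alternatives and the rule for named genes were fixed. Of the entries 774 matched the ESC and EB tables by symbol and 5 by a RefSeq synonym, against 707 and 39 in the sorted tables. Histone genes matched the sorted tables by synonym for 29 of 61. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. Text names Tdg, Trp53, Cdkn1a, Mdm2 and Ccng1 in each comparison, then the 6 genes most raised and the 6 most lowered among those called with at least 1 RPKM in the higher group, no overlap of libraries and no clone or predicted-gene symbol, then called members of lists. One gene that this rule names is not reported here. With fewer than 4 calls, the 4 smallest p among genes that meet these conditions of level and symbol are given as values. Genes of the 2-cell-like list and the EB genes shown per library were chosen after their values were seen.

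Alternatives were other pseudocounts, filters and scalings, no trend, the replicate number as a block, the own table alone and each library left out. Added after seeing the data were limma-voom on recovered reads and, for the lists, other scalings, left-out libraries and the block with an estimated correlation. Peaks were intersected with bedtools 2.31.1 at a minimum of 1 bp, with 1000 seeded circular shifts. The peak lists hold no score, so no test by peak strength was run. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and drawn with matplotlib 3.10.9.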

Results

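RNA was sequenced from E14Tg2A cells, a mouse embryonic stem cell (ESC) line, that had received a control siRNA (siC) or an siRNA against Tdg (siTdg). Tdg encodes thymine DNA glycosylase, a base excision repair enzyme that also removes oxidised forms of 5-methylcytosine. The 20 libraries analysed fell into 10 groups of 2: ESCs at 48 h and at 96 h, embryoid bodies (EBs, aggregates in which ESCs differentiate) at day 11, and ESCs separated by cell-cycle phase into G1 and G2M, each with siC and with siTdg. The series also holds one list of TDG binding peaks and one of p53 binding peaks from chromatin immunoprecipitation of ESCs. Its title names the question, the part TDG plays in p53 activity across the cell cycle. Reads assigned to genes, recovered from the deposited values, ranged from 20818174 to 41433232 per library. Labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Libraries with the same replicate number deviated together from their group means, with correlations from 0.66 for siC phases to 0.95 in EBs. The model holds no term for replicate number, so this shared spread stays in its p-values. A lack of calls therefore does not show that no gene changed. Counts with replicate number as a block are given further below.

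Tdg itself was measured first. At 48 h it stood at 44.7 ± 1.80 RPKM (SD, n = 2) in siC and 10.3 ± 4.16 RPKM (SD, n = 2) in siTdg. At 96 h the means were 40.9 ± 7.24 RPKM and 34.3 ± 8.55 RPKM (SD, n = 2 each). In day 11 EBs they were 36.8 ± 2.39 RPKM in siC and 40.5 ± 4.51 RPKM in siTdg (SD, n = 2 each). In sorted cells Tdg was at 57.2 ± 3.43 RPKM in siC G1, 8.59 ± 1.49 RPKM in siTdg G1, 62.4 ± 0.999 RPKM in siC G2M and 10.5 ± 2.62 RPKM in siTdg G2M (SD, n = 2 each). RPKM values were scaled separately for each deposited table, so levels set side by side across times or siRNAs of sorted cells carry that difference in scale.

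**Figure D1:**
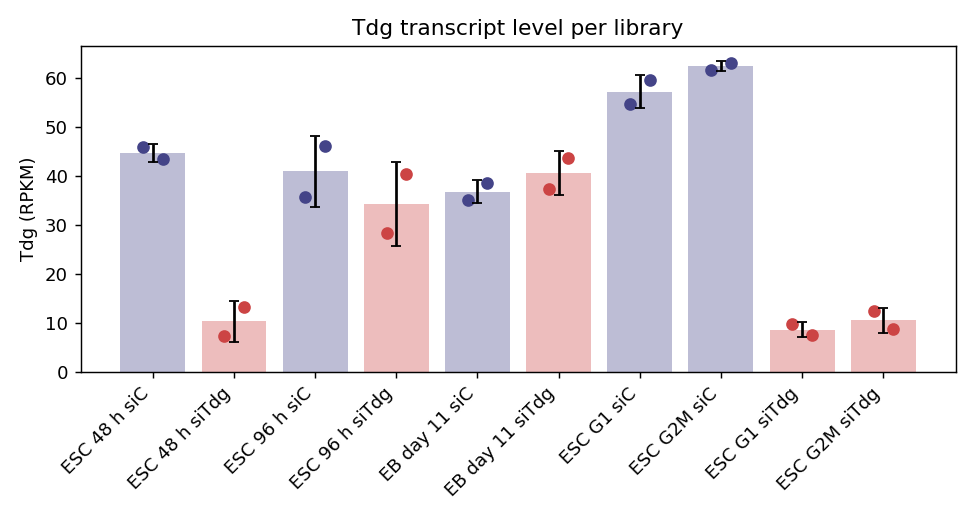
Tdg level in RPKM (y axis) in the 10 groups (x axis). Bars are means, points the 2 libraries and error bars the SD. At 48 h the siTdg mean is 10.3 RPKM against 44.7 RPKM in siC, and at 96 h it is 34.3 RPKM against 40.9 RPKM.

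At 48 h the log2 change of Tdg was -2.12 (SE 0.31), with an adjusted p of 1 by limma. In the authors' deposited table, signed here as siTdg minus siC, Tdg had a log2 change of -2.18 and an adjusted p of 0.000176. Trp53, the gene of p53, had a log2 change of -0.04 (SE 0.29). Its targets Cdkn1a, a cyclin-dependent kinase inhibitor, Mdm2, the ubiquitin ligase of p53, and Ccng1, cyclin G1, had log2 changes of -0.06, 0.02 and 0.16. Nrbp1 was at 28.3 ± 2.16 RPKM in siTdg and 47.3 ± 0.355 RPKM in siC (SD, n = 2 each), and Snhg9, a small nucleolar RNA host gene, at 1.42 ± 0.110 RPKM and 0.251 ± 0.0811 RPKM (SD, n = 2 each). Lst1 had a log2 change of -1.09. Glycolysis genes fell as a group, with 19 of 21 members below 0, a median log2 change of -0.17 and an adjusted camera p of 0.00371. With an estimated correlation that call was lost (adjusted p = 0.924 with an estimated correlation), and 0 of the 21 members passed over all genes or adjusted over the list alone. It was also lost without ESC 48 h siC replicate 1 (median -0.04) and without ESC 48 h siTdg replicate 2 (median -0.05). The 45 p53 targets had a median of -0.05 and an adjusted camera p of 0.432. Among 12190 genes limma, with no term for replicate number, called 0, and 54 had an unadjusted p under 0.05. Without such a term limma-voom on recovered reads called 0 as well. The authors' deposited table holds 113 genes at an adjusted p under 0.05, 10 higher and 103 lower in siTdg. Those include Tnks (log2 change -0.88), Nrbp1 (-0.74), Xrn2 (-0.61) and Hsp90ab1 (-0.54) in the authors' deposited table, the 4 smallest adjusted p, chosen after their values were seen.

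At 96 h Tdg had a log2 change of -0.26 (SE 0.31, adjusted p of 1 by limma). Trp53 had -0.04, Cdkn1a -0.17, Mdm2 -0.16 and Ccng1 -0.10. Among genes meeting the level and symbol conditions, the smallest p were those of Ly6c2 (-0.70), Sult2b1 (-0.63), Pla2g10os (-0.64) and Fbp2 (-0.58). None was called. The p53 target list was lower in siTdg, with 38 of 45 members below 0, a median of -0.15 and an adjusted camera p of 0.000247 (adjusted p = 0.648 with an estimated correlation). G2/M genes were higher (50 of 59 members, median 0.08, adjusted p = 0.000187), as were G1/S genes (30 of 38, median 0.08, adjusted p = 0.000247), cholesterol synthesis genes (20 of 23, median 0.16, adjusted p = 0.000908) and cytosolic ribosomal protein genes (71 of 76, median 0.06, adjusted p = 0.00944, but median 0.00 and no call with quantile normalization). For these 4, in that order, with an estimated correlation adjusted p = 0.610, 0.610, 0.648 and 0.951. Glycolysis genes were lower (15 of 21, median -0.07, adjusted p = 0.00399), and so were primitive streak and mesendoderm genes (5 of 6, median -0.23, adjusted p = 0.0167). For both adjusted p = 0.610 with an estimated correlation, and 0 members of any of the 7 lists passed adjusted over the list alone. Without ESC 96 h siC replicate 1 the medians of p53 targets, cholesterol, ribosomal, G2/M, G1/S, glycolysis and mesendoderm genes were 0.08, -0.13, -0.21, 0.00, -0.02, -0.09 and -0.03, and without siTdg replicate 2 they were 0.13, -0.20, -0.27, 0.02, 0.00, -0.12 and 0.01, with the ribosomal list alone still called, as lower. The glycolysis call was also lost without siC replicate 2 (-0.14) and, with the mesendoderm call, without siTdg replicate 1 (-0.19 and -0.46). Leaving out 1 library sets 2 libraries against a single one, so these medians also hold the difference between replicate numbers. With replicate number as a block all 7 lists were called at the preset correlation, and 0 with an estimated correlation. Limma called 0 of 12190 genes, 11 had an unadjusted p under 0.05, and limma-voom called 0. The authors' deposited table holds 9 genes at an adjusted p under 0.05, 3 higher and 6 lower in siTdg. Named after their values were seen, they include Pclaf, a PCNA clamp associated factor (log2 change 0.67) and Ccne1, cyclin E1 (0.45), and P2rx7 (-0.83), Pros1 (-0.55), Dnmt3l (-0.67) and Plk2 (-0.46) in the authors' deposited table.

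The difference between the 2 times was tested directly. The Tdg effect at 96 h minus that at 48 h was 1.86 on the log2 scale (SE 0.44, adjusted p of 1 by limma). Snhg9 had a difference of -1.47, Nrbp1 of 0.66 and Lst1 of 1.29, while Cdkn1a had -0.11, Mdm2 -0.18, Ccng1 -0.26 and Trp53 0.00. Cholesterol synthesis genes differed upward, with 23 of 23 members above 0, a median of 0.29 and an adjusted camera p of 0.000748, and integrated stress response genes did too (16 of 18, median 0.27, adjusted p = 0.00834). For both lists adjusted p = 0.706 with an estimated correlation, and 0 members passed adjusted over the list alone. Without ESC 96 h siTdg replicate 2 the medians were -0.15 and -0.27, and without ESC 96 h siC replicate 1 they were -0.09 and -0.19. Both calls were lost, too, without ESC 48 h siC replicate 2 (0.17 and 0.09) and without ESC 48 h siTdg replicate 1 (0.11 and 0.07). Limma and limma-voom each called 0 genes, and 15 had an unadjusted p under 0.05 by limma. Across 12190 genes the 48 h and 96 h effects had a Pearson r of 0.30 (SD 0.33 over pairs of single libraries) and a Spearman rho of 0.35. This is a description across genes, which are not independent replicates. The SD also covers pairs of unlike replicate number, so it is not the error of r.

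In day 11 EBs Tdg had a log2 change of 0.13 (SE 0.42), Trp53 -0.13, Mdm2 0.12 and Ccng1 0.18. Endoderm and yolk sac genes were higher in siTdg, with 25 of 31 members above 0, a median of 0.30 and an adjusted camera p of 4.79e-07 (adjusted p = 0.692 with an estimated correlation). By replicate number the median of this list was 0.52 in replicate 1 and 0.07 in replicate 2. Afp, the fetal serum protein alpha-fetoprotein, was at 69.55 and 127.8 RPKM in the siC libraries and at 135.7 and 289.6 RPKM in the siTdg libraries. Embryonic globin Hbb-bh1 was at 1.58 and 216.6 RPKM in siC replicates 1 and 2, and at 4.24 and 413 RPKM in siTdg replicates 1 and 2. Haematopoietic and endothelial genes were higher as a list (14 of 19, median 0.18, adjusted p = 0.0214), as were interferon-stimulated genes (12 of 14, median 0.19, adjusted p = 0.000116), G2/M genes (47 of 59, median 0.14, adjusted p = 0.00266), glycolysis genes (19 of 21, median 0.21, adjusted p = 0.0255) and integrated stress response genes (17 of 20, median 0.18, adjusted p = 0.00881). For these 5, in that order, with an estimated correlation adjusted p = 0.727, 0.692, 0.992, 0.992 and 0.992. Replication-dependent histone genes were lower (27 of 43, median -0.09, adjusted p = 0.00266). For these adjusted p = 0.992 with an estimated correlation, and 0 members of any of the 7 lists passed adjusted over the list alone. The yolk sac call was lost without siC replicate 2 (median 0.12) and without siTdg replicate 1 (0.05), as were those of glycolysis (-0.18 and -0.27), stress response (0.04 and -0.15), interferon-stimulated (0.26 and 0.32) and histone genes (0.09 and 0.04). Without siC replicate 1 or siTdg replicate 2 the G2/M (-0.10 and -0.12) and haematopoietic (0.19 and 0.17) calls were lost, with those of interferon-stimulated genes in the first (0.15) and histone genes in the second (-0.17), while the yolk sac medians were 0.70 and 0.68. Without siTdg replicate 1 the haematopoietic median was 0.02, still called. Such medians also hold the difference between replicate numbers, since 2 libraries then face a single one. With replicate number as a block all 7 lists were called at the preset correlation, and 0 with an estimated correlation. With quantile normalization the glycolysis median was 0.12, not called. Cox4i2 was at 3.71 ± 0.551 RPKM in siTdg and 1.35 ± 0.134 RPKM in siC, and Gli1, a Hedgehog effector, at 2.85 ± 0.679 RPKM and 5.68 ± 0.0266 RPKM (SD, n = 2 each). Npff had a log2 change of -0.98 and Scarna9 was listed at 0 in both siTdg libraries. Cdkn1a had a mean of 84.3 ± 90.7 RPKM in siTdg and 78.4 ± 81.3 RPKM in siC (SD, n = 2 each), so the replicates of one group lay far apart. Limma called 0 of 13300 genes, 20 had an unadjusted p under 0.05, and limma-voom called 0; limma called 1 without siC replicate 2, siTdg replicate 1 or siTdg replicate 2. The authors' deposited table holds 10 genes, 8 higher and 2 lower in siTdg. Afp (log2 change 1.07), Hbb-y (1.35), Hba-x (1.52) and Trf (1.16) are among the higher ones, and Meg3 (-0.84) and Gli1 (-1.02) are the lower ones in the authors' deposited table, all named after their values were seen.

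**Figure D2:**
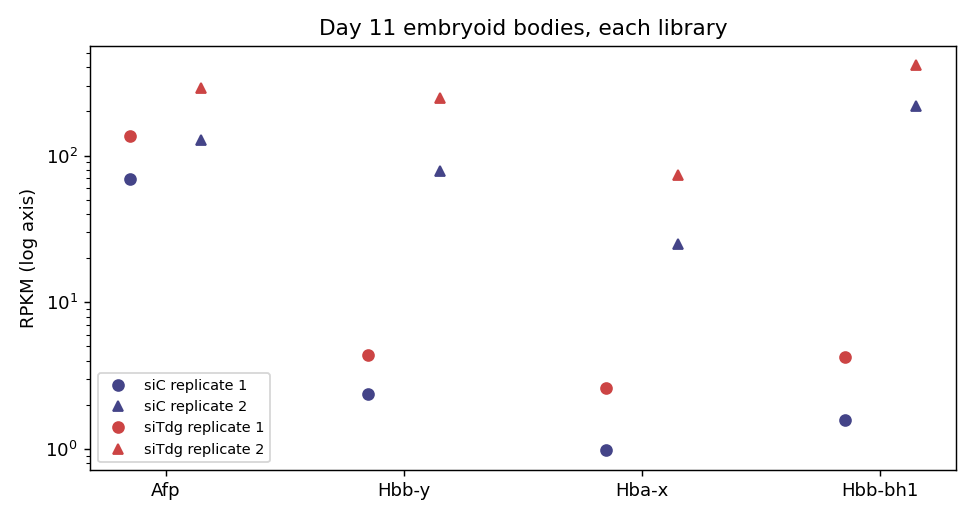
RPKM (log y axis) of Afp, Hbb-y, Hba-x and Hbb-bh1 (x axis) in each of the 4 day 11 EB libraries. Colour marks the siRNA and shape the replicate. Hbb-bh1 is at 1.58 RPKM in siC replicate 1 and 216.6 RPKM in siC replicate 2.

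In sorted siC cells genes of mitosis were higher in G2M. Top2a, the DNA topoisomerase of mitotic chromosomes, rose from 65.0 ± 5.28 RPKM in G1 to 230.5 ± 5.30 RPKM in G2M (SD, n = 2 each), a log2 change of 1.82 (SE 0.14, adjusted p = 0.0167 by limma). Kpna2, a nuclear import receptor, rose by 1.68, Aurkb, the kinase Aurora B, by 1.65, Prc1, a spindle midzone protein, by 1.57, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, and Depdc1b by 1.28 each. Magef1 and Gzmm fell, with log2 changes of -1.60 and -1.59, from 2.58 and 1.98 RPKM in G1. Of 12462 genes limma called 13 higher and 2 lower in G2M. Of the 59 G2/M genes 8 rose and 51 did not pass (24 rose adjusted over the list alone), with a median of 0.31 and an adjusted camera p of 1.88e-20 (adjusted p = 0.524 with an estimated correlation). Replication-dependent histone genes were higher (21 of 21, median 0.59, adjusted p = 1.26e-07), as were naive pluripotency genes (28 of 34, median 0.13, adjusted p = 0.00482) and cytosolic ribosomal protein genes (75 of 76, median 0.12, adjusted p = 0.0221, but median 0.00 and no call with quantile normalization). For these 3, in that order, with an estimated correlation adjusted p = 0.524, 0.524 and 0.815. Lists lower in G2M were the 2-cell-like genes (16 of 17, median -0.54, adjusted p = 3.89e-11, 6 fell adjusted over the list alone), G1/S genes (25 of 38, median -0.07, adjusted p = 0.00112, 6 fell adjusted over the list alone) and p53 targets (35 of 45, median -0.12, adjusted p = 0.000306). For these 3, in that order, with an estimated correlation adjusted p = 0.524, 0.680 and 0.719. Adjusted over the list alone 1 histone gene rose, and 0 naive pluripotency, ribosomal or p53 target genes passed. Cdkn1a was at 84.9 ± 6.69 RPKM in G1 and 69.7 ± 6.77 RPKM in G2M, and Ccng1 at 125.4 ± 18.4 RPKM and 92.5 ± 14.4 RPKM (SD, n = 2 each), neither called. Mdm2 had a log2 change of -0.32, Trp53 of 0.07 and Tdg of 0.12. The authors' deposited table gives Cdkn1a -0.29, Mdm2 -0.32 and Ccng1 -0.44 for G2M minus G1, with adjusted p of 0.00211, 0.000363 and 1.22e-10, among 675 higher and 243 lower genes. The 15 calls became 0 without any 1 of the 4 siC libraries or of the 2 siTdg G2M libraries, 3 in the siC table alone and 17 by limma-voom, and that of Gzmm was lost as well without either siTdg G1 library, by limma-voom and, with that of Ube2c, with no filter. With no filter the 13 called of 20726 genes were 6 higher and 7 lower, 7 of them among the 15. With 1 library left out the log2 change of Top2a lay between 1.74 and 1.9 and that of Aurkb between 1.53 and 1.77. That of Gzmm lay between -1.77 and -1.42. The p53 target and ribosomal calls were lost without siC G1 replicate 1 (medians -0.01 and 0.03) and siC G2M replicate 2 (0.03 and 0.05), the G1/S call without siC G1 replicate 2 (-0.05) and siC G2M replicate 1 (-0.04), and the naive pluripotency call without siC G1 replicate 2 (0.12) and with quantile normalization (0.09).

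Sorted siTdg cells gave 18 genes higher and 3 lower in G2M. Top2a rose by 1.78 (adjusted p = 0.0220 by limma), Aurkb by 1.60, Kpna2 by 1.59, Prc1 by 1.55 and G2e3 by 1.33, while Magef1 and Gzmm had log2 changes of -1.56 and -1.43. With 1 library left out the log2 change of Top2a lay between 1.6 and 1.96. Of the 59 G2/M genes 10 rose and 49 did not pass (29 rose adjusted over the list alone), with a median of 0.40 and an adjusted camera p of 3.26e-21 (adjusted p = 0.519 with an estimated correlation). Histone genes (18 of 21, median 0.37, adjusted p = 0.0013) and naive pluripotency genes (24 of 34, median 0.20, adjusted p = 0.0181) were higher (adjusted p = 0.730 and adjusted p = 0.519 with an estimated correlation). The 2-cell-like genes (16 of 17, median -0.56, adjusted p = 1.34e-10, 8 fell adjusted over the list alone), G1/S genes (25 of 38, median -0.07, adjusted p = 0.000444) and p53 targets (37 of 45, median -0.13, adjusted p = 0.00016) were lower in G2M. For these 3, in that order, with an estimated correlation adjusted p = 0.519, 0.730 and 0.730. Adjusted over the list alone 1 G1/S gene rose and 5 fell, and 0 histone, naive pluripotency or p53 target genes passed. Cdkn1a was at 87.4 ± 4.19 RPKM in G1 and 71.2 ± 4.36 RPKM in G2M (SD, n = 2 each). Mdm2 had a log2 change of -0.29, Ccng1 of -0.42, Trp53 of 0.10 and Tdg of 0.26. In the authors' deposited table, with 481 higher and 102 lower genes, Cdkn1a had -0.30 and Mdm2 -0.29, with adjusted p of 0.113 and 0.121, and Ccng1 -0.42 with an adjusted p of 0.00415. The 21 calls, also 21 by limma-voom, became 2 without siTdg G1 replicate 1, 8 without siTdg G1 replicate 2, 0 without any 1 of the other 6 libraries and 0 in the siTdg table alone. Those of G2e3, Magef1 and Gzmm were lost without any 1 of the 8 libraries, and that of Gzmm with no filter and by limma-voom. The p53 target and histone calls were lost without siTdg G1 replicate 1 (medians -0.06 and 0.22), and the naive pluripotency call without siTdg G1 replicate 2 (0.13), without siTdg G2M replicate 1 (0.10) and with quantile normalization (0.17).

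**Figure D3:**
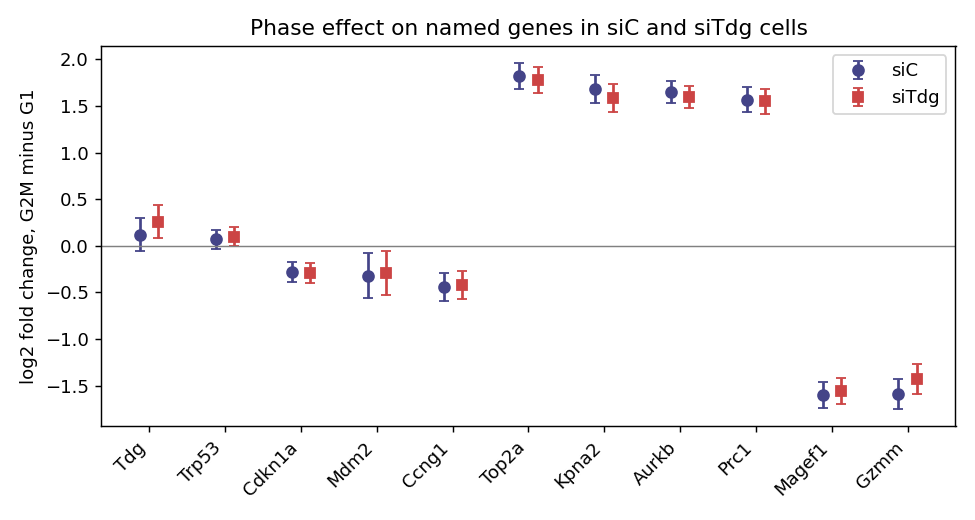
Log2 fold change from G1 to G2M (y axis) of the genes named in both siRNA conditions (x axis), with error bars of 1 SE. Top2a changed by 1.82 in siC and 1.78 in siTdg, and Ccng1 had -0.44 and -0.42.

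Whether the phase effect depended on Tdg was tested as an interaction. The p53 genes had differences near 0: Cdkn1a -0.01 (SE 0.16), Mdm2 0.03 (SE 0.34), Ccng1 0.02 (SE 0.21) and Trp53 0.02 (SE 0.14). Among genes meeting the level and symbol conditions, the smallest p were those of Cnih2 (-0.71), Dnaja4 (-0.52), Hoxd9 (-0.48) and Platr20 (0.64). None was called. The p53 target list had a median difference of -0.01 and an adjusted camera p of 0.642. Cytosolic ribosomal protein genes had a lower phase effect in siTdg (75 of 76, median -0.16, adjusted p = 4.44e-10), as did histone genes (15 of 21, median -0.13, adjusted p = 0.0334). For both lists adjusted p = 0.908 with an estimated correlation, and 0 members passed adjusted over the list alone. Without siTdg G1 replicate 2 the medians were 0.11, called as higher, and 0.07. The ribosomal call was lost without siTdg G2M replicate 1 (-0.05), and the histone call without siC G1 replicate 1 (-0.05), siC G2M replicate 1 (-0.05) or siTdg G2M replicate 2 (-0.01) and with quantile normalization (-0.15). Limma called 0 of 12462 genes, 36 had an unadjusted p under 0.05, and limma-voom called 0. Across genes the phase effects in siC and siTdg had a Pearson r of 0.70 (SD 0.27 over pairs of single libraries) and a Spearman rho of 0.70. That SD, too, covers pairs of unlike replicate number and is not the error of r.

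Within each phase siTdg was then compared with siC across the 2 tables, after scaling the libraries to one median. Tdg fell in G1, with a log2 change of -2.65 (SE 0.17, adjusted p = 0.0145 by limma), and in G2M, with one of -2.54 (SE 0.17, adjusted p = 0.0187), and it was the 1 gene called in each, by limma-voom as well. Its call in G1 was lost without any 1 of the 4 siC libraries or of the 2 siTdg G1 libraries, and in G2M without any 1 of the 4 siC libraries or siTdg G2M replicate 2. With 1 library left out its log2 change lay between -2.77 and -2.52 in G1 and between -2.76 and -2.32 in G2M. The 2-cell-like genes, a set active in the 2-cell embryo and in rare ESCs, were higher in siTdg in G1 (16 of 17, median 0.75, adjusted p = 3.51e-20 by limma's camera) and in G2M (16 of 17, median 0.69, adjusted p = 3.54e-31). The list gave adjusted p = 0.320 in G1 and adjusted p = 0.149 in G2M with an estimated correlation. Adjusted over the list alone 15 of the 17 rose in each phase, and over all genes 0 did. Zscan4a had log2 changes of 0.84 in G1 and 0.86 in G2M, Tdpoz3 of 0.83 and 0.63 and Dux, a transcription factor of this set, of 0.77 and 0.34. Members of the Zscan4 and Usp17l families share near-identical sequence, and those of the Pramel family related sequence, so their single values are uncertain. For the same reason the counts of members are not counts of independent genes. The estimated correlation of the list was 0.316, against the preset 0.01. The broadly expressed members Eif1a, a general translation factor, and Zswim7 had log2 changes of -0.04 and 0.17 in G1. The siC G1 replicates differed by a median of 0.46 over the list. Usp17lb was at 4.34 ± 0.204 RPKM in siTdg G1 and 2.54 ± 0.207 RPKM in siC G1 (SD, n = 2 each). In G2M the log2 changes of Usp17lb and Pramel31 were 0.67 and 0.76. Urml and Pramel6 had log2 changes of 0.74 and 0.73 in G1, and Noxred1 of -0.81 in G2M, none called. Ribosomal protein genes were higher in G1 (74 of 76, median 0.30, adjusted p = 1.58e-10) and in G2M (73 of 76, median 0.10, adjusted p = 0.0192), and cholesterol synthesis genes lower in G1 (16 of 22, median -0.14, adjusted p = 0.000492) and in G2M (20 of 22, median -0.10, adjusted p = 0.00148). For both lists adjusted p = 0.819 in G1 and adjusted p = 0.998 in G2M with an estimated correlation. In G1, integrated stress response genes (18 of 19, median 0.16, adjusted p = 0.0102) and p53 targets (32 of 45, median 0.12, adjusted p = 0.0228) were higher and p53 pathway regulators lower (13 of 18, median -0.12, adjusted p = 0.0102). For these 3 lists adjusted p = 0.819 with an estimated correlation. Of these 5 lists 0 members passed adjusted over the list alone. In G1 the p53 target and cholesterol calls were lost without siC G1 replicate 2 (medians 0.00 and -0.03) and siTdg G1 replicate 1 (0.06 and 0.03), and the stress response and p53 regulator calls without siC G1 replicate 1 (0.04 and -0.08) and siTdg G1 replicate 2 (-0.01 and -0.05), the latter ending the ribosomal call as well (-0.01). In G2M the ribosomal call was lost without siC G2M replicate 1 (0.03) and siTdg G2M replicate 2 (-0.04), and the cholesterol call without siC G2M replicate 2 or siTdg G2M replicate 1 (-0.02 each). In G1 and G2M Cdkn1a had log2 changes of 0.07 and 0.03, Mdm2 of 0.11 and 0.10, Ccng1 of 0.11 and 0.10 and Trp53 of -0.09 and -0.10.

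**Figure D4:**
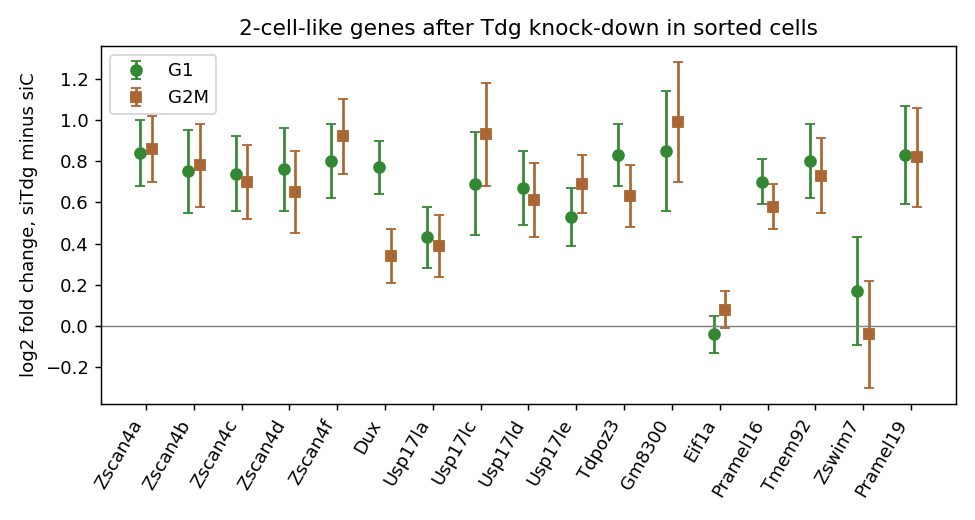
Log2 fold change of siTdg minus siC (y axis) for the 17 tested 2-cell-like genes (x axis) in G1 and G2M, with error bars of 1 SE. In each phase 16 of the 17 lie above 0, with medians of 0.75 and 0.69.

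TDG and p53 binding was compared through the deposited peak lists, on mouse genome build mm9 per the submitters' processing notes. Of 673 TDG peaks 580 (86.2%) overlapped a p53 peak by at least 1 bp, and those were 580 (11.8%) of 4897 p53 peaks. In 1000 circular shifts of the TDG peaks the most overlaps were 37 and the median 1.0, giving a one-sided permutation p of 0.001, the smallest they can give. Centres of 555 TDG peaks lay within 100 bp of a p53 peak centre. The 93 TDG peaks without overlap had a median centre distance of 107000 bp, the shortest being 1025 bp. All peaks are 400 bp wide and carry no score, so the first 3 overlapping TDG peaks in file order are named: chromosome 1 from 6476712 to 6477111, from 9628981 to 9629380 and from 13491989 to 13492388 (mm9). Genes at these positions were not analysed here. Each factor has one list, so replicates could not be compared, and the shifts do not model open chromatin or mappability.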

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

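The test of a single library in this part was chosen after the result was seen. By camera at the preset correlation, 4 gene lists passed a test of the difference itself, and none did with an estimated correlation. The siTdg effect at 96 h minus that at 48 h had a median of 0.29 in cholesterol synthesis genes and 0.27 in integrated stress response genes (adjusted p = 0.706 for both with an estimated correlation), and of -0.15 and -0.27 without ESC 96 h siTdg replicate 2. The phase effect in siTdg minus that in siC had a median of -0.13 in replication-dependent histone genes (adjusted p = 0.908 with an estimated correlation), and of 0.07 without siTdg G1 replicate 2.

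Cytosolic ribosomal protein genes had a phase effect with a median of -0.16 in siTdg minus siC (adjusted p = 0.908 with an estimated correlation). With siTdg G1 replicate 2 left out the median was 0.11, the highest over the 8 libraries, as it would be if a single library stood apart. This does not decide the cause of the direction, since both siTdg G2M libraries then face siTdg G1 replicate 1 alone. In replicate 1 the medians of these genes on the log2 scale, G1 then G2M, were 9.87 and 10 in siTdg and 9.74 and 9.94 in siC. In replicate 2 they were 10.42 and 10.2 in siTdg and 9.94 and 10.03 in siC. By these medians the phase effect was lower in siTdg in both replicate numbers. Random lists matched on transcript length and mean expression had a median of -0.11 and a 2.5th percentile of -0.13, so short abundant genes moved the same way. The genes of these lists were drawn one by one, while the ribosomal genes had an estimated correlation of 0.871. The percentiles therefore cannot decide whether -0.16 lies beyond length and level. A dependence of the phase effect on Tdg stays open, untested beyond these libraries.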

How the results depend on the processing

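The alternatives with limma-voom, and those of the gene lists with other scalings, left-out libraries or a replicate block with an estimated correlation, were chosen after seeing the data. With 1 library left out, 478 values of single genes and 227 of lists kept direction and side of the threshold, 119 and 44 kept direction and lost a call, and 46 and 29 turned direction, by sign or, for a list, by its test as well. Under the other alternatives 681 and 106 kept both, 21 and 131 lost a call, 19 values of genes gained one, and 2 turned, Cdkn1a with quantile normalization in EBs (-0.03) and in the phase interaction (0.02). Counts of called genes moved by over 1.5 times in few other settings: without a filter to 4 at 96 h, 4 for 96 h minus 48 h and 7 for the phase interaction, and in the own table alone to 3 for siC phases and 0 for siTdg phases, where fewer libraries share the spread. Other pseudocounts, a filter at 1 RPKM, no trend, quantile normalization, median-ratio scaling and limma-voom kept each count within 1.5 times. Called lists numbered 0 with an estimated correlation, 0 with fry and 0 with a block and an estimated correlation, in each of the 9 comparisons, and 5 within G2M with quantile normalization. Even the G2/M genes of sorted cells lost their call with an estimated correlation and with fry. Of these 59 genes 24 in siC and 29 in siTdg rose in G2M adjusted over the list alone. Losing a call with an estimated correlation or fry therefore does not show that a list was unchanged. Over genes called in siC or siTdg phases the effects had an r of 0.99, against 0.70 over all genes, by construction from large effects. Replicate numbers are shared between groups, but labels do not say that a number marks a culture or day. Deviations of same-numbered libraries from their group means correlated by 0.85 at 48 h, 0.93 at 96 h, 0.95 in EBs, 0.66 in siC phases and 0.72 in siTdg phases. With a replicate block the called genes numbered 280 at 48 h, 15 at 96 h, 14 for 96 h minus 48 h, 150 in EBs, 1076 for siC phases, 1686 for siTdg phases, 1 for the phase interaction, 2 within G1 and 3 within G2M, and called lists 6 at 48 h, 11 at 96 h, 9 for 96 h minus 48 h and 1 for the phase interaction. With 1 library left out, where a lone library is assumed to vary like the others, called genes ranged from 0 to 1 in EBs, 0 to 17 for siC phases, 0 to 8 for siTdg phases and 0 to 1 within G1 and within G2M, and stayed at 0 at 48 h, at 96 h and for both interactions. Called lists ranged from 0 to 4 at 48 h, 5 to 12 at 96 h, 1 to 10 for 96 h minus 48 h, 5 to 10 in EBs, 5 to 7 for siC phases, 6 to 8 for siTdg phases, 1 to 6 for the phase interaction, 4 to 7 within G1 and 3 to 5 within G2M. Medians of the lists that turned ranged at 96 h from -0.20 to 0.61 for cholesterol, -0.27 to 0.39 for ribosomal, 0.00 to 0.18 for G2/M, -0.02 to 0.23 for G1/S, -0.48 to 0.01 for mesendoderm and -0.36 to 0.13 for p53 target genes. For 96 h minus 48 h they ranged from -0.15 to 0.71 for cholesterol and -0.27 to 0.62 for stress response genes, and in EBs from -0.12 to 0.38 for G2/M, -0.27 to 0.85 for glycolysis, -0.15 to 0.53 for stress response and -0.33 to 0.09 for histone genes. They ranged from -0.42 to 0.11 for ribosomal and -0.41 to 0.07 for histone genes in the phase interaction and from -0.28 to 0.03 for p53 targets in siC phases. Within G1 they ranged from 0.00 to 0.17 for p53 targets, -0.26 to 0.03 for cholesterol, -0.01 to 0.61 for ribosomal and -0.01 to 0.33 for stress response genes, and within G2M from -0.04 to 0.23 for ribosomal genes. Single genes that turned, none of them called, ranged at 48 h from -0.34 to 0.22 for Cdkn1a, -0.20 to 0.24 for Mdm2, -0.05 to 0.38 for Ccng1 and -0.19 to 0.11 for Trp53, and at 96 h from -0.42 to 0.07 for Cdkn1a, -0.25 to 0.06 for Ccng1 and -0.36 to 0.28 for Trp53. For 96 h minus 48 h they ranged from -0.39 to 0.17 for Cdkn1a and -0.40 to 0.04 for Mdm2, and in EBs from -1.39 to 1.46 for Cdkn1a, -0.57 to 0.81 for Mdm2 and -0.65 to 0.40 for Trp53. In the phase interaction they ranged from -0.11 to 0.09 for Cdkn1a, -0.26 to 0.31 for Mdm2, -0.14 to 0.18 for Ccng1, -0.05 to 0.09 for Trp53 and -0.11 to 0.38 for Tdg, within G1 from -0.02 to 0.16 for Cdkn1a, -0.12 to 0.35 for Mdm2 and -0.02 to 0.24 for Ccng1, and within G2M from -0.06 to 0.11 for Cdkn1a, -0.16 to 0.37 for Mdm2 and -0.04 to 0.24 for Ccng1. With 1 library left out the 2-cell-like medians kept their direction and call, from 0.50 to 0.98 within G1 and 0.60 to 0.75 within G2M. Leaving out 1 library of a compared group sets 2 libraries against a single one. The ranges and turns with 1 library left out therefore also hold the difference between replicate numbers. In EBs Cdkn1a was at 135.8 RPKM in siC and 148.4 RPKM in siTdg in replicate 1, against 20.89 and 20.11 RPKM in replicate 2. For other changes not said to follow from construction, the cause was not tested. TDG peaks overlapping p53 peaks numbered 573 by 0.5 of the peak, 581 with 500 bp of widening and 573 by centre. As all peaks are 400 bp wide, the conditions by 0.5 of the peak and by centre are nearly the same. Their equal counts follow by construction. A stricter peak threshold was not run, since the lists hold no score. What depth limits was not tested.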

Other observations

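The tests on 2-cell-like genes of scaling and of shared reads, and that of the EB cell mixture, were chosen after the result was seen, and the test by gene family was added after that on the whole list. In unsorted cells the 8 tested 2-cell-like genes had a median log2 change of 0.42 at 48 h (8 of 8 above 0, adjusted p = 0.16 by camera) and of -0.18 at 96 h (2 of 8 above 0, adjusted p = 0.812). In the authors' deposited table at 0 h, Trp53 was higher in SG2M than in G1 by 0.22 with an adjusted p of 0.035, Top2a by 2.54, and Cdkn1a had -0.16, Mdm2 -0.01 and Ccng1 -0.04 with adjusted p of 0.227, 0.951 and 0.808.

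The higher 2-cell-like genes in sorted siTdg cells are a pattern to follow up. Scaling of the libraries is argued against, since on the deposited scale the median of all genes was 0 in G1 and 0.01 in G2M. A factor per library would move all genes alike. The list's smallest median over 3 scalings and both phases was 0.65, but these scalings differed too little to move it far. Reads moved between copies within a gene family are argued against too, because the reads of the Zscan4 and of the Usp17l family, each summed over 5 members, were at least 1.26 times those of siC in each pair of libraries. The sum over the whole list gave a smallest ratio of 1.07 but decides nothing, as Eif1a, a general translation factor, held 62.1% of its reads. The spread between cultures of one group cannot be told apart from the effect, with 2 libraries per group and median differences between replicates of 0.46 in siC G1, 0.13 in siTdg G1, 0.09 in siC G2M and 0.02 in siTdg G2M, each below the effects of 0.75 in G1 and 0.69 in G2M, and an effect of Tdg on these genes stays a hypothesis.

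Yolk sac and endoderm genes higher in siTdg EBs are less firm. Scaling is argued against, since the median of all genes was 0.02 and the smaller list median under 2 other scalings was 0.30. A variable cell mixture between EB cultures is left open. The median absolute difference between the replicates of a group was at least 1.12, but this decides nothing, as the replicate differences of these genes had an r of 0.96 between siC and siTdg. Whether only one replicate number differed cannot be told apart, with medians of 0.52 in replicate 1 and 0.07 in replicate 2. Tdg was not lower in these EBs (log2 change 0.13), and an effect of the earlier knock-down stays open as untested.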
